A study of Mus musculus with 6 samples.

How the data were processed

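Total RNA from 6 primary mouse OPC cultures, 3 from cerebrum and 3 from spinal cord, was extracted with a column kit, turned into biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. GenomeStudio 2011.1 is named in the submitters' processing notes. The deposited values used here were linear probe intensities in the authors' processed value table, whose columns are named by sample. Their scale was read from the values, which ran from 36.5 to 49682 on every array with an upper quartile of 162.7 and medians of 64.5, so that the 6 arrays had nearly equal distributions. How the authors normalised the intensities, and whether background was removed, is not given in the sources used here. The median intensity of olfactory receptor (Olfr) probes, genes not expected in OPC, was 52.3 to 53.0 per array, so background appeared to remain in the values, and the fold change of a dim gene is understated. A further deposited table held 12 columns of per-sample intensities and detection p-values whose names match no sample's labels. These were not used in any step, and only the gene symbol column of that table was read.

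The design written before the data were examined assumed scanner intensities with control-based normalisation and a filter on detection p-values. Because those columns could not be tied to samples, log2 of the value table, which had been planned as an alternative, became the reported setting, and the filter was replaced after seeing the data. A probe was tested if its log2 intensity exceeded the 95th percentile of the 1302 Olfr probes of the same array (67.2 to 68.6 in linear intensity) on at least 3 of the 6 arrays, which left 20988 of 45281 probes. Gene symbols were those of the array's table, brought up to date through NCBI's gene table for assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of 30869 symbols 16219 matched a current symbol, 5718 matched a synonym of a single gene and 8932 matched none. Probes without a match (3165 of those tested, of which 40 of 484 probes past the threshold) entered the fit and the adjustment but no gene count. No genome build is named in the sources used here, so no coordinates are given.

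Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), spinal cord minus cerebrum, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A gene was represented by its brightest tested probe, which gave 11226 genes. Of 124 called genes with other tested probes, 67 had another probe past the threshold in the same direction and 0 in the opposite direction. Genes whose other tested probe did not pass include Gpr149, Enpp2, Sox2, Sema6d and Sfrp1. A gene was taken as not above background in a tissue when all its probes lay below the floor on all 3 arrays. A fold was given as a bound when the probe used lay below the floor on all 3 arrays of one tissue, a rule tied to the probe after seeing the data. The median standard error of a log2 fold change was 0.11. Fold changes are those of probe intensities, and levels of different probes were not compared.

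Replicate numbers stand for a shared cell preparation per the labels' design text, which pools 3 to 4 pups. The deviations of same-numbered samples from their tissue means correlated with 0.53, 0.21 and 0.50 across probes, and differently numbered samples with -0.45 to 0.03. The numbers were therefore taken as pairs. The reported fit had no block, as fixed before the data were examined, and values from the fit with the preparation as a block (median standard error 0.09) stand beside results where they change a call or move a count by more than 1.5 times.

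The lists of genes were written before the data were examined. They cover Hox genes, forebrain and hindbrain or spinal cord patterning factors, OPC, myelin, astrocyte, microglia, neuron, endothelial, meningeal, Schwann and ependymal markers, cell cycle, migration in 5 functional lists and their union, cholesterol synthesis, interferon, hypoxia, neurotransmitter and potassium channels, Wnt and BMP, and the Y-linked genes with Xist. Lists with at least 5 tested genes (23 lists) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which does not compare a list with other genes. Fisher's exact test of called genes per list, 10000 random lists matched on mean intensity and arrangements of the samples with tissue in the model were added after seeing the data. Named genes followed a rule fixed in advance. It took the 12 largest differences per direction among called genes whose samples did not overlap between the tissues, leaving out clone names, then up to 4 called members per list by adjusted p, or the 2 largest changes where none was called, and Pdgfra, Cspg4, Olig2, Sox10, Xist and Ddx3y always. The 6 Hox genes that did not pass, Prrx1 under the block, Eif2s3y and Enpp6 in the plot by preparation, and the genes of the closing section were picked after their values were seen, unless the rule names them. Results for some of the genes and lists are not reported here.

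The fit was tested on simulated data made from the means and residual spread of the 20988 tested probes, with shifts between preparations as large as the fitted ones, which include noise, and 200 changed probes in each of 5 runs. Changes of 0.5 (log2) were recovered in 14.0%, of 1 in 99.7% and of 2 in 100% of cases, with 0% false calls. With the preparation as a block 95.8% of changes of 0.5 were recovered with 7.33% false calls. On data with no change 0 of 23 lists passed camera. Those data had independent genes and no shifts between preparations, so they do not show how camera behaves with either. Alternatives were the preparation as a block, normexp background correction with offsets of 16 and 50, no filter, a stricter filter (above the 99th percentile of Olfr probes on all 3 arrays of a tissue), eBayes without a trend or with robust estimation, array weights, the mean of a gene's probes, adjustment over named genes only, and each array left out in turn. The normexp corrections, the stricter filter and the adjustment over named genes were chosen after seeing the data.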

Results

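Gene expression was measured on Illumina bead arrays in oligodendrocyte precursor cells (OPC), the proliferating and migratory glial cells that later form myelin. The cells were primary mouse cultures from 2 tissues of C57BL/6 pups aged 6 to 8 days, cerebrum (3 samples) and spinal cord (3 samples). All 6 cultures grew for 7 days with 10 ng/ml PDGF-AA and were kept proliferating by it, since this growth factor drives OPC division. Each preparation pooled 3 to 4 pups and gave 1 cerebrum and 1 spinal cord sample with the same replicate number. Of 45281 probes per array, between 20343 (44.9%, spinal cord replicate 3) and 21081 (46.6%, spinal cord replicate 2) lay above the background floor. The median standard deviation between the 3 samples of a tissue was 0.14 (log2) in cerebrum and 0.10 in spinal cord, and the number of arrays limits the precision. Samples of the same tissue correlated across tested probes with r from 0.988 to 0.996 and samples of different tissues with r from 0.986 to 0.991, where probes are not independent replicates. The first principal component held 42.4% of the variance and separated the tissues. The second held 32.7% and ran from cerebrum replicate 1 (18.2) to cerebrum replicate 3 (-25.2), which lay farthest from the other samples, with spinal cord replicate 1 at 12.5 and spinal cord replicate 3 at -8.39.

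The series asked which genes differ between OPC of cerebrum and spinal cord, with those relevant to migration in view. Homeobox genes of the Hox clusters, which set position along the body axis, were the most different. Hoxa7 was at least 64.6-fold higher in spinal cord OPC (log2 intensity 12.10 ± 0.11, SD, n = 3) than in cerebrum OPC, where it was not above background (6.02 ± 0.03, SD, n = 3). Hoxa5 was at least 37.3-fold higher, Hoxb7 at least 28.5-fold, Hoxd8 at least 25.1-fold, Hoxc6 at least 21.2-fold and Hoxc9 at least 16.6-fold. In the other direction Nrn1, which encodes the neurite-promoting protein neuritin, was at least 6.26-fold higher in cerebrum OPC (8.73 ± 0.17 against 5.66 ± 0.06, SD, n = 3 each), with spinal cord OPC not above background. The adjusted p in limma was 5.61e-12 for Hoxa7 and 3.3e-09 for Nrn1. Bounds are given wherever the probe used lay below the floor on all 3 arrays of one tissue, and they compare the brighter tissue with that floor or with the probe's own value if higher.

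Among 11226 named genes tested, 331 differed at an adjusted p under 0.05, of which 210 were higher and 121 lower in spinal cord OPC. In all 331 the 3 samples of one tissue lay above the 3 of the other, which also fixes the direction in all 3 same-numbered pairs. Over all tested genes 1748 (15.6%) were separated in this way, against 10% for 6 samples in arbitrary order, a value that ignores the pairing by preparation. A difference of 2-fold or more was found in 88 genes, 55 higher and 33 lower in spinal cord OPC. With the preparation as a block 711 genes passed (408 higher, 303 lower), including all 331. Without 1 array the count was 202 (cerebrum replicate 2), 574 (cerebrum replicate 3), 216 (spinal cord replicate 1) or 196 (spinal cord replicate 2), while the count at 2-fold or more stayed between 86 and 95.

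The 12 largest differences towards spinal cord OPC held 11 Hox genes and Adcy8, which encodes an adenylyl cyclase and had a log2 fold change of 2.86 ± 0.11 (SE), 7.28-fold, with 8.90 ± 0.17 in spinal cord against 6.04 ± 0.08 in cerebrum (SD, n = 3 each). The Hox genes below those named above were Hoxc10 (at least 11.2-fold), Hoxa2 (log2 fold change 2.83 ± 0.10, SE), Hoxb2 (2.76 ± 0.10), Hoxb5 (at least 5.14-fold) and Hoxd10 (at least 4.03-fold). In cerebrum replicates 1 and 3 Adcy8 (5.97 and 6.015) and Hoxa2 (6.005 and 5.989) lay below the floor, so their fitted changes are no exact sizes. Moxd1, a relative of dopamine beta-hydroxylase, fell by 2.69 ± 0.14 (log2, SE) from cerebrum to spinal cord. Eya1, a transcriptional coactivator and phosphatase, fell by 2.36 ± 0.12. The orphan receptor gene Gpr149 fell by 2.33 ± 0.14, while its other tested probe did not pass the threshold. Otx1, a forebrain homeobox gene, was at least 3.86-fold higher in cerebrum OPC. Atp10b had a log2 fold change of -1.97 ± 0.12 (SE), Srpk3 -1.90 ± 0.19, Chst7 -1.87 ± 0.18, Pmel -1.75 ± 0.13, the semaphorin receptor gene Plxnb3 -1.52 ± 0.13 and the lysophosphatidic acid receptor gene Lpar4 -1.49 ± 0.13. The adjusted p (limma) of these genes was 7.38e-05 or lower.

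**Figure D1:**
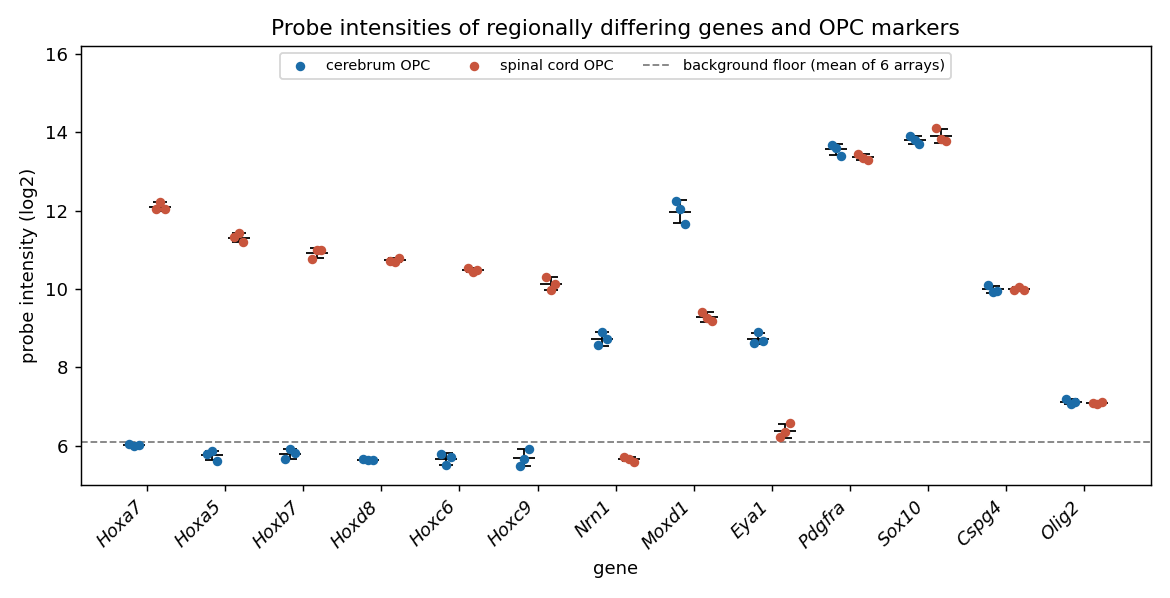
Log2 probe intensity (y axis) of 13 genes (x axis) in cerebrum OPC (blue) and spinal cord OPC (red), with a point for each of the 3 samples, the mean as a horizontal line, the SD as a bar and the mean background floor as a dashed line. Hoxa7 reached 12.10 in spinal cord OPC and lay below the floor in cerebrum OPC, Nrn1 showed the opposite arrangement, and Sox10 lay near 13.8 in both tissues.

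Genes that mark position along the neural tube were followed in 3 lists fixed before the data were examined. Of 25 tested Hox genes 19 were higher in spinal cord OPC and 0 lower (22 and 0 when adjusted over the list alone), and 15 of the 19 were not above background in cerebrum OPC. The 6 that did not pass were Hoxa6, Hoxb3, Hoxc8, Hoxc13, Hoxd11 and Hoxa13, and of these Hoxa6 passed with the preparation as a block (adjusted p = 0.0259). Of 14 forebrain patterning factors 7 were lower in spinal cord OPC and 0 higher (9 and 0 adjusted over the list alone), among them Otx2 (at least 1.75-fold higher in cerebrum) and Nr2e1 (log2 fold change -1.13 ± 0.13, SE). Nr2e1 lay below the floor in spinal cord replicate 2 (5.941), so its fitted change is no exact size. Of 19 hindbrain and spinal cord factors outside the Hox clusters 7 were higher and 0 lower (7 and 1 adjusted over the list alone, and with the preparation as a block). Irx5 rose by 2.31 ± 0.13 (log2, SE) and Irx3 by 2.29 ± 0.19, both Iroquois homeobox genes, followed by Tshz2 with 1.16 ± 0.10, and Dbx2 was at least 1.51-fold higher. A set test with a preset correlation (camera) gave an adjusted p of 6.5e-74 for the Hox list, 4.45e-13 for the forebrain list and 6.42e-06 for the hindbrain and spinal cord list. With an estimated correlation the adjusted p was 0.000755, 0.041 and 0.484 in that order, and with the preparation as a block as well it was 0.0569, 0.388 and 0.514. In the 9 other arrangements of the 6 samples into 3 and 3, with tissue in the model, the preset test passed up to 5 of 23 lists, with adjusted p down to 2.49e-09 (chosen after seeing the data). Called genes were also more frequent in each of the 3 lists than among all other tested genes (Fisher's exact test, two-sided, adjusted p of 1.74e-23, 4.01e-07 and 3.88e-06, chosen after seeing the data).

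Of the markers most used for OPC, Pdgfra, Sox10, Cspg4 and Olig2 did not pass between the tissues. Pdgfra, the receptor for PDGF-AA, had a log2 intensity of 13.56 ± 0.15 in cerebrum and 13.36 ± 0.07 in spinal cord OPC (SD, n = 3 each), a log2 fold change of -0.20 ± 0.10 (SE, adjusted p = 0.586). Sox10, a transcription factor of the oligodendrocyte lineage, had 0.11 ± 0.11 (adjusted p = 0.898), the NG2 proteoglycan gene Cspg4 0.01 ± 0.10 (adjusted p = 0.994) and Olig2 -0.03 ± 0.09 (adjusted p = 0.986). The sign of the last 2 turned in some leave-one-out fits. Of 22 OPC markers 0 were higher and 3 lower in spinal cord OPC, with the same numbers when adjusted over the list alone. Gpr17, a receptor of cells committed to differentiation, fell by 1.37 ± 0.23 (log2, SE, adjusted p = 0.00495), the retinoid-binding protein gene Rlbp1 fell by 0.84 ± 0.12 (0.00113) and Sox5 fell by 0.57 ± 0.11 (0.0132). The list had an adjusted p of 0.0738 in camera, 0.0495 with the preparation as a block and 0.494 with an estimated correlation. Without 1 array its adjusted p passed as well, at 0.04998 without cerebrum replicate 2 and 0.0211 without cerebrum replicate 3. Of 15 markers of differentiated oligodendrocytes and myelin, Mbp (myelin basic protein) was higher in spinal cord OPC by 1.04 ± 0.11 (adjusted p = 0.000111) and Enpp2 (autotaxin) was lower, with -0.65 ± 0.15 (adjusted p = 0.0349). Adjusted over the list alone 3 were higher and 4 lower, and with the preparation as a block 4 and 4. The camera test of this list gave an adjusted p of 0.418, and 0.04998 without cerebrum replicate 2, against 0.807 with an estimated correlation and all arrays. Sox5 lost its call in 2 and Enpp2 in 4 of the 6 fits without 1 array, with adjusted p up to 0.111 and 0.222, both without spinal cord replicate 2.

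Markers of other cell types that such cultures can hold were followed in 7 lists. Of 22 microglia and macrophage markers 4 were above the floor, and 0 of these differed (0 adjusted over the list alone), with log2 fold changes of 0.12 ± 0.11 (SE) for Laptm5 and 0.09 ± 0.11 for Csf1r. Of 12 astrocyte markers 0 were higher and 2 lower in spinal cord OPC (2 and 2 adjusted over the list alone, and with the preparation as a block). Sox9, a glial transcription factor, fell by 1.25 ± 0.18 (log2, SE, adjusted p = 0.00155) from 13.74 ± 0.41 to 12.49 ± 0.26 (SD, n = 3 each), and Acsbg1 fell by 0.79 ± 0.12 (0.0027). Of 13 neuron markers 1 was higher, Gap43 with 0.40 ± 0.10 (adjusted p = 0.0483), and 1 lower, Npy with -0.82 ± 0.11 (0.000937), against 2 and 2 adjusted over the list alone and 2 and 1 with the preparation as a block. Npy lay below the floor in spinal cord replicate 2 (6.028), so its fitted change is no exact size. Of 8 Schwann cell and neural crest markers Mbp and Gap43, which stand on other lists too, were higher and Sox2 lower (-0.70 ± 0.14, adjusted p = 0.0166), against 2 and 2 adjusted over the list alone, and with the preparation as a block. The share of called genes in this list exceeded that among other genes (Fisher's exact test, adjusted p = 0.00419). None of 6 endothelial and mural markers (Cdh5 -0.05 ± 0.09, and Tek with a bound of at least 1.07-fold towards cerebrum, adjusted p = 0.309), 3 meningeal and fibroblast markers (Prrx1 -0.56 ± 0.15, Col1a1 -0.23 ± 0.12) and 6 ependymal markers (Rarres2 -0.15 ± 0.12, Dynlrb2 -0.14 ± 0.11) passed. Adjusted over the list alone these gave 0, 1 lower (Prrx1) and 0. The endothelial and mural list includes Cspg4, which stands on the OPC list too. Its other tested genes had tissue means of 5.97 to 6.34 (log2), near the floor, so their lack of difference says little. Prrx1 passed with the preparation as a block (adjusted p = 0.00372) and without cerebrum replicate 3 (0.000213). The camera adjusted p was 0.876 for astrocyte, 0.779 for neuron, 0.821 for Schwann, 0.361 for endothelial and 0.418 for ependymal markers. The microglial and meningeal lists were too short for it. Median and mean log2 fold change had opposite signs for astrocyte (0.05 and -0.07) and neuron markers (0.02 and -0.02). Gap43 lost its call in 5 and Sox2 in 3 of the 6 fits without 1 array, with adjusted p up to 0.253 (without spinal cord replicate 2) and 0.103 (without spinal cord replicate 3).

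Of 218 tested genes on the migration list, which joins 5 functional lists, 21 were higher and 5 lower in spinal cord OPC. The largest were Fgf1, a fibroblast growth factor, with a log2 fold change of 1.99 ± 0.13 (SE, adjusted p = 1.02e-06), the integrin gene Itga9 with 1.55 ± 0.10 (1.75e-06) and Fgfr2, a fibroblast growth factor receptor, with 1.53 ± 0.10 (1.91e-06). The cadherin gene Cdh8 was at least 1.71-fold higher in spinal cord OPC and not above background in cerebrum OPC (8.28e-06). In total 11.9% of the list differed, against 2.77% of all other tested genes (Fisher's exact test, two-sided, adjusted p = 1.38e-08, chosen after seeing the data). Among 10000 random lists matched on mean intensity the median number of called genes was 6 and the highest 18, against 26 observed, with a permutation p of 1e-04, the smallest they can give. Both comparisons treat genes as independent, while the estimated inter-gene correlation of the list was 0.097. In lists not chosen for migration the share was 0% for cell cycle, cholesterol synthesis, interferon, endothelial and ependymal genes. It was 6.25% for hypoxia, 7.69% for Wnt and BMP and 12% for channel genes. For markers it was 13.3% (myelin), 13.6% (OPC), 15.4% (neuron), 16.7% (astrocyte) and 37.5% (Schwann). The excess passed Fisher's exact test for Schwann markers (adjusted p = 0.00419) but not for OPC (0.0594) or astrocyte markers (0.0902). A share of 11.9% was thus also reached outside the migration list, in marker lists with few called genes. The list as a whole was not shifted one way (median log2 fold change 0.02, camera adjusted p = 0.0738). Adjusted over the list alone 31 were higher and 11 lower, and with the preparation as a block 33 and 16. Without 1 array the number higher was 12 (cerebrum replicate 2) or 11 (either of spinal cord replicates 1 and 2) and the number lower 15 (cerebrum replicate 3). The list passed camera without cerebrum replicate 1 (adjusted p = 0.00363), cerebrum replicate 2 (0.04998) or spinal cord replicate 3 (0.0289). It did not pass in the remaining fits without 1 array, with adjusted p up to 0.657. With an estimated correlation and all arrays the adjusted p was 0.677.

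**Figure D2:**
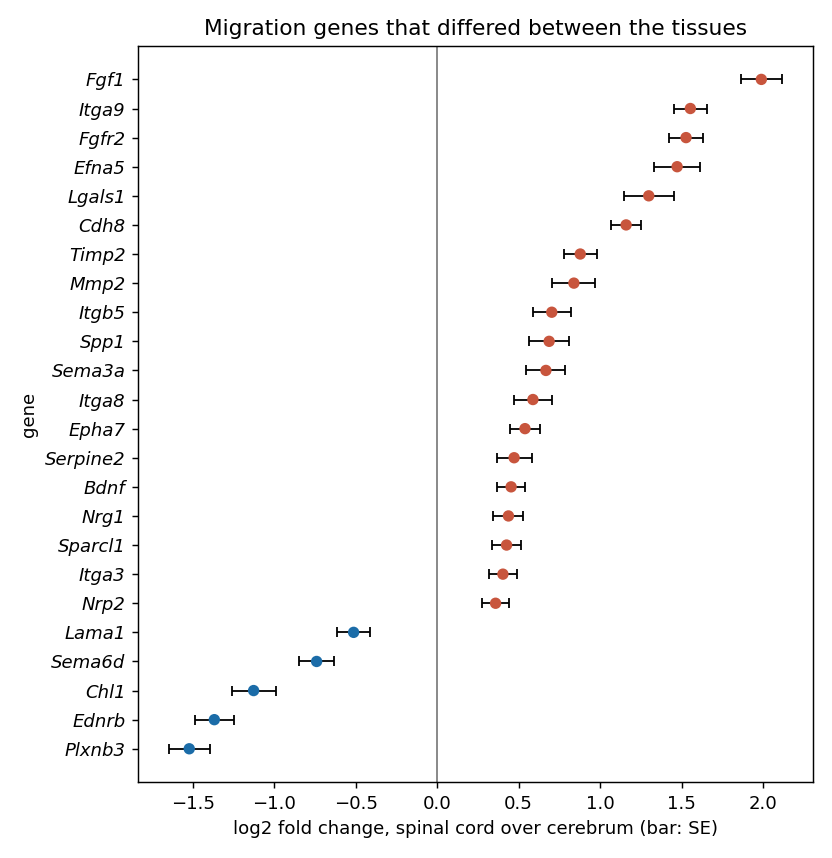
Log2 fold change of spinal cord over cerebrum OPC (x axis, bars SE) for 24 migration genes (y axis) with an adjusted p under 0.05, red for higher and blue for lower in spinal cord. The values run from -1.52 (Plxnb3) to 1.99 (Fgf1), and for Bdnf, Cdh8, Chl1, Epha7, Itgb5 and Nrp2 the probe was not above background in the dimmer tissue, so that the fitted change is no exact size.

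Within the migration list, growth factor and chemokine signals had 5 higher and 1 lower of 29 tested genes (6 and 4 adjusted over the list alone, 5 and 3 with the preparation as a block). Lgals1 (galectin 1) rose by 1.30 ± 0.15 (log2, SE, adjusted p = 0.00033), and the endothelin receptor gene Ednrb fell by 1.37 ± 0.12 (2.57e-05), from 13.47 ± 0.05 to 12.10 ± 0.25 (SD, n = 3 each). Of 48 semaphorin, netrin, Slit and Eph guidance genes 4 were higher and 2 lower (5 and 2 adjusted over the list alone, 5 and 4 with the block). Plxnb3 was lower, Efna5, which encodes ephrin A5, higher by 1.47 ± 0.14 (5.59e-05), Sema6d at -0.74 ± 0.11 (0.00205) and Epha7 at least 1.18-fold higher (0.00535). Of 35 integrins and adhesion molecules 5 were higher and 1 lower (5 and 2 adjusted over the list alone, 6 and 3 with the block). Itgb5 was at least 1.4-fold higher (0.00439) and the adhesion gene Chl1 at least 1.81-fold higher in cerebrum OPC (0.000345). Of 44 matrix and matrix-remodelling genes 5 were higher and 1 lower (9 and 2 adjusted over the list alone, 8 and 3 with the block). The metalloproteinase inhibitor gene Timp2 rose by 0.88 ± 0.10 (0.000269), the metalloproteinase gene Mmp2 by 0.84 ± 0.13 (0.00315) and Spp1 (osteopontin) by 0.69 ± 0.12 (0.00932), and the laminin gene Lama1 fell by 0.51 ± 0.10 (0.0153). The Fisher adjusted p was 0.000773 for growth factors, 0.00693 for guidance, 0.0019 for adhesion and 0.00495 for matrix genes. None of the 4 was shifted one way in camera, with adjusted p of 0.418, 0.201, 0.201 and 0.0972 in the same order. The matrix list passed without cerebrum replicate 1 (0.0376) and without cerebrum replicate 2 (0.04998), against 0.677 with an estimated correlation and all arrays. In fits without 1 array the call of Spp1 was lost in 2 of 6 and that of Lama1 in 3 of 6, with adjusted p up to 0.0698 and 0.102, both without spinal cord replicate 2.

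Genes of glutamate, GABA and potassium channels, through which OPC respond to neurons, had 0 of 25 higher and 3 lower in spinal cord OPC (2 and 5 adjusted over the list alone, and with the preparation as a block). The AMPA receptor gene Gria2 fell by 1.02 ± 0.12 (log2, SE, adjusted p = 0.00025), the NMDA receptor gene Grin3a fell by 0.71 ± 0.10 (0.00155) and the potassium channel gene Kcna6 fell by 0.77 ± 0.12 (0.00402). Of 30 cell cycle genes none passed, with Ccnd2 at -0.65 ± 0.21 (adjusted p = 0.22) and Ccnd1 at 0.40 ± 0.15 (0.298). Adjusted over the list alone the cell cycle count was also 0, against 1 higher (Ccnd1, 0.00175) and 1 lower (Ccnd2, 0.00362) with the preparation as a block, and Ccnd2 passed without cerebrum replicate 3 (6.05e-06). The cell cycle list had a camera adjusted p of 0.0816, 0.0495 with the block and 0.484 with an estimated correlation. None of 20 cholesterol synthesis genes passed (Dhcr7 -0.21 ± 0.16) or did so adjusted over the list alone. Dhcr7 passed only without cerebrum replicate 3 among the fits without 1 array (0.0258). None of 14 interferon and antigen presentation genes passed (Rsad2 0.33 ± 0.09, Psmb9 0.33 ± 0.12), against 1 higher adjusted over the list alone and 2 higher with the preparation as a block. These were the same 2 genes (0.0411 and 0.045). Psmb9 (0.0293) and the list (0.0471) also passed without cerebrum replicate 3, against 0.494 for the list with an estimated correlation and all arrays. Of 16 hypoxia and glycolysis genes the peptide hormone gene Adm was at least 1.67-fold higher in cerebrum OPC (0.0071), the same 1 gene when adjusted over the list alone, and 2 were lower with the block. Of 26 Wnt and BMP pathway genes Dkk3 was higher (0.60 ± 0.10, 0.00494) and Sfrp1 lower (-0.58 ± 0.12, 0.0216), against 4 and 1 adjusted over the list alone and 2 and 1 with the block. Sfrp1 lost its call in 4 of the 6 fits without 1 array, with adjusted p up to 0.147 without spinal cord replicate 3. The camera adjusted p was 0.225 for channels, 0.911 for cholesterol synthesis, 0.0816 for interferon, 0.269 for hypoxia and 0.0842 for Wnt and BMP genes, the last at 0.0376 without cerebrum replicate 1 and 0.677 with an estimated correlation.

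Xist, Eif2s3y and Ddx3y varied more between preparations than between the tissues. Xist, which is expressed from the inactive X chromosome, had log2 intensities of 5.70 and 5.71 in cerebrum and spinal cord replicate 1, 11.26 and 11.56 in replicate 2 and 10.93 and 10.17 in replicate 3. The Y-linked Ddx3y had 9.42 and 9.66, 7.42 and 7.78, and 8.48 and 9.10 in the same order, and Eif2s3y had 10.29 and 10.32, 5.56 and 5.69, and 8.47 and 9.27. None of the 5 tested genes of this list passed between the tissues (Ddx3y 0.41 ± 0.47, adjusted p = 0.932, camera adjusted p of the list 0.593), and the count adjusted over the list alone was 0. With the preparation as a block Ddx3y passed (adjusted p = 0.0174).

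**Figure D3:**
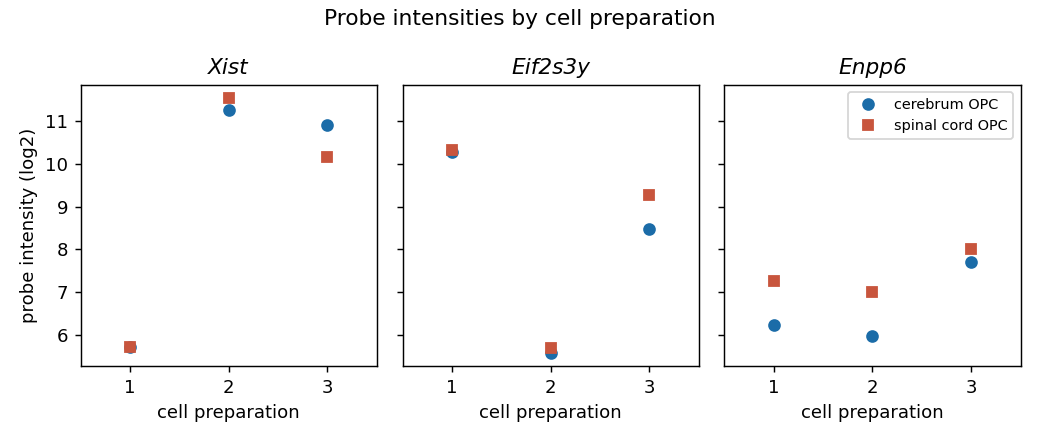
Log2 probe intensity (y axis) of 3 genes in each of the 3 cell preparations (x axis), with 1 point per sample, circles for cerebrum OPC and squares for spinal cord OPC. Xist lay at background in preparation 1 and at 10.17 or more in the other preparations, and Enpp6 was highest in preparation 3 in both tissues.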

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

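The normexp corrections, the stricter filter and the adjustment over named genes were chosen after seeing the data. All 331 genes kept their direction under every alternative that tested them (316 of them under the stricter filter). The count was 330 or 331 with normexp correction, 331 without a filter, 317 with the stricter filter, 333 without a trend, 332 with robust estimation, 324 with probes averaged and 356 adjusted over named genes only. With the replicate block, which pairs the samples of one preparation, it was 711 (408 higher, 303 lower), with 33 migration genes higher and 16 lower and 5 lists shifted in camera (none with an estimated correlation as well, lowest adjusted p 0.0569), and beyond the calls given with the results it called Mag (adjusted p = 0.000249), Enpp6 (0.00034) and Cd9 (0.0192) between the tissues and changed no other call among the genes and lists named in the text. With array weights it was 978 (540 higher, 438 lower), with 34 and 22 migration genes. The cause was not tested, although the block takes the spread between preparations out of the error. Leaving out 1 array gave 196 to 574 genes (131 to 312 higher, 64 to 262 lower), 86 to 95 at 2-fold or more, 11 to 24 migration genes higher and 4 to 15 lower, 3 to 7 lists shifted and an adjusted p of 0.00363 to 0.657 for the migration list. With an estimated correlation 2 lists were shifted in place of 3, and fry found 16 lists with changes in either direction, among them the migration list (adjusted p = 7.83e-07). Of the genes named by the rule fixed in advance, leaving out the sex-linked list, 9 past the threshold lost it in at least 1 alternative. Among the others of these genes 7 passed in at least 1, a count that leaves out genes picked after their values were seen. Reversals concerned lists and genes near 0 that were not called. With array weights the direction turned for myelin (adjusted p = 0.553), astrocyte (0.736), Schwann (0.963), ependymal (0.999) and cholesterol lists (0.26), for Csf1r (log2 fold change -0.0586), Cdh5 (0.0195) and Olig2 (0.0024). It turned for astrocyte markers with the replicate block (0.948), with averaged probes (0.975) and in fry (0.934), for cholesterol genes with averaged probes (0.894), for neuron (0.725) and ependymal markers (0.867) without a filter and for Schwann markers with the stricter filter (0.743). Leaving out 1 array turned at least 1 of 6 fits for these results, with adjusted p of 0.04998 to 0.92 (myelin), 0.551 to 0.993 (astrocyte), 0.495 to 0.924 (neuron), 0.508 to 0.885 (Schwann), 0.135 to 0.709 (cholesterol), 0.133 to 0.979 (Y-linked) and 0.042 to 0.834 (1 further list), and with log2 fold changes of -0.00709 to 0.171 (Csf1r), -0.0194 to 0.0642 (Cspg4) and -0.0539 to 0.00344 (Olig2). The cause was not tested. Detection-based filters, control-based normalisation, median centring of scanner values and a slide block were not run, since scanner columns match no sample by name and no slide is named. Signal over background limits the sizes of dim genes such as the Hox genes in cerebrum OPC, and genes below the floor on all arrays were not tested.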

Other observations

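The comparison between preparations, the look beside the Hox clusters, the splits at 2-fold or more or with tissue in the model and the neighbouring pairs among preparation genes were chosen after results had been seen, and the direction of the leading preparation genes was known before the test of pup sex. In a fit with tissue and preparation, 563 of 11226 genes differed between the 3 preparations (limma, adjusted p under 0.05), of which 18 also differed between the tissues. The adjusted p given per gene is that of any difference among the 3 preparations. Preparation 3 against the mean of preparations 1 and 2 was not tested for single genes. Enpp6, a marker of newly formed oligodendrocytes, was higher in preparation 3 than in the mean of preparations 1 and 2 by 1.60 (log2) in cerebrum and 0.89 in spinal cord OPC (adjusted p = 0.000155), Fa2h, an enzyme of myelin lipids, by 1.08 and 0.41 (0.0119), Mt3 by 1.02 and 0.60 (0.0038) and the tetraspanin gene Cd9 by 0.81 and 0.45 (0.0045). Of 15 myelin markers 5 differed between preparations, among them Mag, Cldn11, Fa2h and Enpp6, and all 5 lay above the mean of preparations 1 and 2 in preparation 3, Cldn11 by only 0.022 in cerebrum and 0.0044 in spinal cord OPC (Fisher's exact test, adjusted p = 0.00707 over 23 lists). The whole list was shifted in camera (adjusted p = 0.000755, 0.577 with an estimated correlation), with a median of 0.34 in cerebrum and 0.07 in spinal cord OPC, and it was also lower in preparation 2 than in 1 (0.00197, 0.754 with an estimated correlation). Other lists passed the comparison of preparation 3 too, among them the migration list (0.0071), the matrix list (0.0275) and the hindbrain and spinal cord list (0.0404), all lower, and none of the 23 did so with an estimated correlation (lowest adjusted p 0.577). Of 30 cell cycle genes 5 differed, 4 of them lower in preparation 3 (Fisher's exact test, adjusted p = 0.12).

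Several genes beside called genes on the chromosome were called in the same direction. Irx3 (2.29), Irx5 (2.31), the long non-coding RNA gene Crnde between them (1.32) and Mmp2 (0.84), the next tested gene, were all higher in spinal cord OPC (log2 fold change). Plxnb3 (-1.52) and its neighbour Srpk3 (-1.90) were both lower, and Cpne8 (1.32) with Kif21a (0.61) and Grb10 (0.87) with Cobl (0.91) were both higher. Skap2, which lies at one end of the Hoxa cluster, rose by 1.98 ± 0.15 (SE, adjusted p = 7.92e-06), while of 40 tested genes within 5 tested genes of the ends of the 4 Hox clusters it was the only 1 called.

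The split of the 6 samples by tissue gave 331 called genes, and the highest of the other 9 among all 10 splits into 3 and 3 gave 0. For differences of 2-fold or more the values were 88 and 0, and in each case 1 split reached the real value, the real one itself, but 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 pairs, with the preparation as a block, tissue gave 711 genes and the highest other 0. Each other split holds 2 samples of one tissue against 1, so it keeps part of the tissue difference and leaves the rest in its error. With tissue in the model, 1 of the 9 gave 647 genes and the others 0.

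For lists passing camera with the preset correlation, the split by tissue gave 3, 8 of the 10 splits gave as many, and the highest other gave 7. Of the splits that part all 3 pairs the highest other gave 6, and with the block tissue gave 5 and the highest other 6. With tissue in the model the 9 other splits gave 0 to 5 lists, 4 of them at least 3, so that lists also pass on differences other than tissue. A list near the threshold of that test cannot be told apart from such variation. The Hox list (adjusted p = 6.5e-74 by tissue) passed in none of these 9 (lowest adjusted p 0.0694). The hindbrain and spinal cord list did pass with cerebrum replicate 1 and spinal cord replicates 1 and 2 together (camera adjusted p = 0.00799).

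The 563 genes that differed between preparations could reflect the sex of the pooled pups, since Xist, Eif2s3y and Ddx3y of preparation 3 lay between those of preparations 1 and 2 in both tissues. Preparation 1 had Xist at background. In preparation 2 Kdm5d (5.92 and 5.66) and the Eif2s3y probe used lay below the floor. Above the floor there were the Ddx3y probe used (7.42 and 7.78), Uty (6.26 and 6.29) and another Eif2s3y probe (6.17 and 6.16). Uty (6.35 and 6.64) and that Eif2s3y probe (6.46 and 6.47) were little higher in preparation 1, so they say little about sex. The other Ddx3y probes lay below the floor on every array. Whether preparation 2 held female pups alone is therefore open. If sex were the cause, preparation 3 would lie between the others in other genes too. Outside the sex-linked list it did so in 5.01% of 559 genes in cerebrum and 15.2% in spinal cord OPC, below the 33.3% that an arbitrary order gives, which argues against pup sex as the main cause. A batch of arrays or labelling shared by same-numbered samples stays open. Over Olfr probes the deviations of same-numbered samples correlated between -0.012 and 0.0133, but a batch need not move probes at background, and no label names one, so batch and preparation cannot be told apart. No biological explanation other than pup sex was tested, and a different maturity of the cultures is one that remains.

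A hypothesis drawn from the Irx genes is that genes beside a called gene may share its regional difference. Outside the Hox clusters 16 pairs of adjacent tested genes were called in the same direction, against a median of 4 and a 95th percentile of 8 in 10000 random placements of the calls (permutation p = 1e-04, the smallest they can give). The annotated spans overlapped in 0 of the 16 pairs, which argues against probes that read an overlapping neighbour. The run from Irx3 to Mmp2, which holds the Irx genes behind the hypothesis, gave 3 of the pairs. These 3 are counted in the 16, and no p without them was computed. Another pair, Fzd10 and Fzd10os, shares a family name. Genes that differed between preparations gave 21 such pairs against a median of 14 (permutation p = 0.0643), so that some adjacency without regional difference stays open, as do transcripts that run on past annotated ends.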
